A study of Homo sapiens with 25 samples.

How the data were processed

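ChIP-seq was run on NB4 cells after 24 h of treatment, with antibodies against H3K4me1, H3K4me2, H3K4me3 and H3K27ac in 5 conditions each, against LSD1 in 2 conditions and against GFI1 in untreated cells. Of the 25 samples, 23 had a peak list, and the 2 input samples entered no comparison. Samples were grouped by antibody and treatment as the labels give them, with 1 library per group. The title of the H3K4me3 combination sample names RA at 1 µM, while its treatment field and the design text name 0.01 µM; it was grouped by the treatment field, and a wrong dose in that library would change what its H3K4me3 values mean. The dose of MC_2580 is not given in the sources used here.

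Per the submitters' processing notes, the tools used before deposit were bcl2fastq 2, CASAVA 1.8, FastQC 0.11.5 and 0.10.0, Bowtie 1.0.1 and MACS 1.4.1, with the hg18 build. The notes name no role or order for them. Each deposited list gives chromosome, start, end, a peak name numbered by the caller and a score, and the score is the authors' value per peak, on the scale of the caller's -10 times log10 of the peak's p-value, with a floor of 50 in the histone and GFI1 lists. Each list belongs to 1 library, and no pooling of libraries is named. The score piles up at 3100, which 30.6% of the H3K4me3 peaks in DMSO reach, so that strong peaks are not ranked among themselves. Some scores run higher, up to 3233.06, and whether these mean stronger peaks than 3100 is not known here. The score was used only to rank and filter peaks within a list. In the LSD1 lists only 24.7% (DMSO) and 26.1% (MC_2580) of the numbered peaks remained, with lowest scores of 234 and 357, so a filter not given in the sources used here had been applied, and it differed between the lists. A minimum score of 100 therefore removes no LSD1 peak. A start below 0 in 8 peaks of 3 H3K27ac lists was set to 0. Chromosome ends in the lists differ from the gene table at hand, which is on GRCh38.p14. No coordinates were converted, and gene names, fixed gene lists, promoter windows and cell type markers need gene positions on hg18 and were not used here.

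From the lists, overlaps were computed with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures drawn with Matplotlib 3.10.9. Peaks overlapping by at least 1 base counted as shared. A treated peak without a DMSO peak of the same antibody was gained and a DMSO peak without a treated peak was lost, and the log2 ratio of these counts summarised a treatment. The Jaccard index was taken on covered bases. For regions gained in a pair of treatments, the peaks of the 5 lists of a mark were merged, and the number gained in both was set beside the product of the single numbers over the regions absent in DMSO and over all merged regions. It was also set beside 1000 simulated sets in which every library called each region independently with that region's own detection rate, scaled to the library's length and held at 1 for regions called in all 5 lists. These sets do not keep the numbers of gained regions. GFI1 peaks were shifted 1000 times around each chromosome for the overlap with LSD1, and their centres along the joined H3K4me2 regions of DMSO. LSD1 sites with an H3K4me3 peak in DMSO were called promoter-type and the others distal-type, a definition by mark and not by gene position. The regions named in the text followed a rule: in each mark and treatment the highest-scoring gained and lost peak and the 100 kb windows with the most gained and lost peaks, and for LSD1 and GFI1 the 3 highest-scoring shared, gained and lost peaks, with ties broken by chromosome and start. As many peaks tie at 3100, several named peaks are the first by position among equals. Peaks named as highest-scoring with a score above 3100 may not be the strongest. No regions prone to false signal were filtered out, and the named peaks were not checked for such signal. Not every region the rule takes is printed.

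Shares have 95% exact binomial intervals and differences between site classes have 95% normal intervals, both covering counting error only. Peaks are not replicates, so no p-value is given. The overlap code was tested on simulated lists of 40000 peaks, in which 5000 planted losses and 3000 planted gains were all recovered. The rules, tests and alternatives were fixed before the data were examined, except where the text says otherwise. The alternatives were a minimum score of 100 in every list, a 50% reciprocal overlap, joining of peaks within 1 kb, a one-sided threshold, lists of equal length, histone peaks reduced to 500 bases on either side of their centre, a Jaccard index over regions, and autosomes only. Added after seeing the data were 1 minimum score for both LSD1 lists, H3K27ac peaks on H3K4me1 only, the comparison set of H3K4me1 regions without LSD1 or GFI1, the strata of LSD1 sites by width and by histone mark, and the retention difference standardised over strata. The score quartiles belonged to the fixed plan, but their reading as a test of weaker peaks was written after their result was seen. The test over strata of width and H3K4me3 was written after the lists were examined but before its result was seen. Alternative promoter windows were not run, since they need gene positions.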

Results

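The series followed chromatin in NB4, an established human cell line of acute promyelocytic leukemia whose cells respond to retinoic acid (RA). Cells were kept for 24 h in the solvent DMSO, in MC_2580, an inhibitor of the histone demethylase LSD1 (KDM1A), in RA at 0.01 µM, in RA at 1 µM, or in MC_2580 with RA at 0.01 µM, called the combination below. Chromatin immunoprecipitation with sequencing (ChIP-seq) was run with antibodies against H3K4me1, H3K4me2, H3K4me3 and H3K27ac in all 5 conditions, against LSD1 in DMSO and MC_2580, and against GFI1, a transcriptional repressor that recruits LSD1, in untreated cells. H3K4me1 and H3K4me2 mark enhancers and promoters, H3K4me3 mainly promoters, and H3K27ac active elements of either kind. Each antibody and condition had 1 library, so no difference between conditions could be set against a replicate spread, and the values describe these libraries. Intervals given with shares are 95% exact binomial intervals and cover counting error only. All positions are on hg18, and gene annotation on that build was not used here.

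The 23 peak lists held between 12562 and 72810 peaks. H3K4me1 lists held 54181 to 72810 peaks and covered 161 to 211 Mb. The H3K4me2 lists had 39302 to 50736 peaks and covered 52.2 to 61.4 Mb, and those of H3K4me3 had 21688 to 29872 peaks and covered 63.9 to 101 Mb. The H3K27ac lists differed most in length, from 24552 peaks with MC_2580 to 55793 with RA at 0.01 µM, which is 2.27-fold, against 1.29-fold to 1.38-fold for the other marks. LSD1 had 12562 peaks in DMSO and 18822 with MC_2580, and GFI1 had 29601. The LSD1 lists kept only part of the numbered calls, with peak numbers running to 50877 in DMSO and 72074 with MC_2580, and their lowest scores were 234 and 357 against 50 in the other lists. Read numbers are not given in the sources used here, so sequencing depth is unknown, and a longer list can reflect a deeper or cleaner library as well as more marked regions.

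The first comparison asked which marked regions appeared or disappeared with each treatment. For H3K4me1, the combination had the most gains, 15957 peaks with no DMSO counterpart against 4490 DMSO peaks that were lost, a log2 ratio of 1.83. MC_2580 alone gained 4626 and lost 7553 (log2 ratio -0.71), RA at 0.01 µM gained 7101 and lost 11223 (-0.66), and RA at 1 µM gained 9200 and lost 8081 (0.19). Covered bases relative to DMSO were 0.99 with MC_2580, 0.79 and 0.88 with RA at 0.01 and 1 µM, and 1.04 in the combination. RA at 1 µM thus covered less than DMSO despite its excess of gained peaks. Of 4 gained H3K4me1 peaks tied at the top score in the combination, the first by position lay on chromosome 10 from 125811509 to 125826253. This region also carried H3K4me1, H3K4me2, H3K4me3 and H3K27ac peaks in both single RA treatments and none of the 4 in DMSO or MC_2580. The same held on chromosome 16 from 65022943 to 65029879, the highest-scoring gain with RA at 1 µM, where the 4 marks were called in the 3 RA-containing conditions only. The 100 kb window with the most H3K4me1 gains in the combination ran from 48400001 to 48500000 on chromosome 20, with 13 gained peaks, and 1 of 2 windows with the most gains under RA at 1 µM ran from 74000001 to 74100000 on chromosome 17, with 10. The highest-scoring lost peak, on chromosome 6 from 42998242 to 43012221, was missing in both RA at 1 µM and the combination, while its H3K4me2, H3K4me3 and H3K27ac peaks were called in every condition. A window with 6 losses under MC_2580, the highest count and shared with 1 other window, ran from 153700001 to 153800000 on chromosome 1, with 10 H3K4me1 peaks in DMSO and 4 with MC_2580. The sign was not stable for RA alone: a 50% reciprocal overlap turned the ratio of RA at 0.01 µM to 0.22, and a minimum score of 100 turned that of RA at 1 µM to -0.012.

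For H3K4me2, gains outnumbered losses most with MC_2580, with 11317 gained and 4469 lost peaks (log2 ratio 1.34). The combination gained 10544 and lost 5848 (0.85), RA at 1 µM gained 10184 and lost 7919 (0.36), and RA at 0.01 µM gained 5618 and lost 8017 (-0.51). Covered bases ranked otherwise, at 1.05 of DMSO with MC_2580, 1.08 in the combination, 0.92 with RA at 1 µM and 0.94 with RA at 0.01 µM. With RA at 1 µM the list thus had more peaks than DMSO but covered less. The highest-scoring H3K4me2 gain with MC_2580 lay on chromosome 6 from 37030100 to 37032334. That position had an LSD1 peak in both conditions and a GFI1 peak of score 3028, and its H3K4me3 peak was likewise the highest-scoring H3K4me3 gain with MC_2580. H3K27ac was called there with MC_2580, with RA at 0.01 µM at a score of 53.2, and in the combination, but not in DMSO or with RA at 1 µM. The RA-containing conditions gained a different region, on chromosome 1 from 153415815 to 153419147, which was the highest-scoring H3K4me2 gain with RA at 0.01 µM and, from 153415695 to 153419166, 1 of 3 tied at the top with the combination. It had H3K4me1 in all 5 conditions and H3K4me2 and H3K4me3 in the 3 with RA. On chromosome 1 from 27821801 to 27823324, 1 of 4 gains tied at the top with RA at 1 µM, H3K4me3 was again called in the 3 RA-containing conditions only. Windows with the most gains lay on chromosome 21 from 45100001 to 45200000 for RA at 1 µM (17 peaks) and on chromosome 16 from 80000001 to 80100000 for the combination (16 peaks). On chromosome 17 from 76900001 to 77000000, MC_2580 gained 12 H3K4me2 peaks and RA at 0.01 µM lost 14, both the highest counts of those comparisons. The window was densely called throughout, with 26 H3K4me2 peaks in DMSO, 32 with MC_2580 and 19 with RA at 0.01 µM, so net changes were smaller. A minimum score of 100 gave H3K4me2 log2 ratios of 2.70 for MC_2580, -0.17 and 1.04 for RA at 0.01 and 1 µM, and 1.75 for the combination, and a 50% reciprocal overlap gave 1.03, -0.15, 0.47 and 0.48. With the one-sided threshold the ratio of RA at 0.01 µM was -0.012, so its excess of losses did not hold there.

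For H3K4me3, every treatment had many gains and few losses. MC_2580 gained 10000 peaks and lost 478 (log2 ratio 4.39), RA at 0.01 µM gained 8101 and lost 861 (3.23), RA at 1 µM gained 6716 and lost 1328 (2.34), and the combination gained 7170 and lost 1365 (2.39). The DMSO list was the shortest of the 5, and 90.2% of its peaks were called in all 4 treatments. Gained peaks were weak within their own lists: their median score with MC_2580 was 89.5, against 2521 for the peaks shared with DMSO. This held in the other marks too, where median scores over the treatments were 69.8 to 95.1 for gained peaks and 208 to 840 for shared ones. Lost DMSO peaks were weak as well. Over all marks and treatments their median scores were 58.35 to 89.58, against 318 to 985 for retained DMSO peaks. Among gains tied at the top score, 11 with RA at 0.01 µM and 5 with the combination, the first by position fell on the same place of chromosome 1, from 17506674 to 17511616 and from 17506667 to 17513312, a region with H3K4me1 and H3K4me2 in all 5 conditions and LSD1 in both. With RA at 1 µM the first of 13 tied gains was chromosome 1 from 183649745 to 183657606, where H3K4me2 was also called in the 3 RA-containing conditions and not in DMSO or MC_2580. The highest-scoring loss with MC_2580, on chromosome 4 from 48798853 to 48803111, was also that of RA at 1 µM and carried a GFI1 peak but no other histone mark in any condition. The 100 kb window from 48800001, which overlaps it, held 19 GFI1 peaks and no H3K4me1 or H3K4me2 peak. H3K4me3 was called there 10 times in DMSO, 5 with MC_2580, 9 and 5 with RA at 0.01 and 1 µM, and 9 in the combination. Whether these are false calls was not tested. With a 50% reciprocal overlap the log2 ratios were 1.17 to 1.60.

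For H3K27ac, MC_2580 stood on the other side from the rest. It gained 2738 peaks and lost 11474, which is 35.0% of the DMSO list (log2 ratio -2.07), whereas RA at 1 µM gained 12910 and lost 6852 (0.91) and the combination gained 15266 and lost 6960 (1.13). RA at 0.01 µM gained 30048 and lost 6012 (2.32). The peaks lost with MC_2580 were weak in DMSO, with a median score of 81.5 against 578 for the retained ones. Of the 11474, 4099 scored at least 100. Of the peaks gained with RA at 0.01 µM, 35.5% (35.0 to 36.1%) lay on an H3K4me1 peak of any condition, against 64.4% with MC_2580, 69.7% with RA at 1 µM and 67.5% with the combination. When H3K27ac peaks off H3K4me1 were left out, a choice made after the data were seen, its log2 ratio was 1.16 and those of MC_2580, RA at 1 µM and the combination were -2.17, 1.09 and 1.24. Among the H3K27ac peaks named next as highest-scoring, those scored from 3116 to 3230 lie above 3100 and may not be the strongest. The highest-scoring gain of the combination lay on chromosome 12 from 123219505 to 123229062 and that of RA at 0.01 µM on chromosome 2 from 84909486 to 84915263. Both regions had H3K27ac in the 3 RA-containing conditions and neither DMSO nor MC_2580. RA at 1 µM had its highest-scoring gain on chromosome 8 from 6809581 to 6817140. With MC_2580 the highest-scoring gain was a 16190-base peak on chromosome 5 from 14967395 to 14983584, with LSD1 in both conditions and GFI1, and of the RA-containing conditions only the combination had H3K27ac there. The highest-scoring loss with MC_2580, on chromosome 9 from 19142968 to 19157169, was called in DMSO, both RA doses and the combination. A peak on chromosome 2 from 213527757 to 213536439 was the highest-scoring loss of both RA at 0.01 µM and the combination and was called in DMSO, MC_2580 and RA at 1 µM. The first of 8 losses of RA at 1 µM tied at the top lay on chromosome 5 from 1360990 to 1373766 and was called in the other 4 conditions. A 50% reciprocal overlap gave log2 ratios of -1.22 for MC_2580, 1.28 and 0.56 for RA at 0.01 and 1 µM, and 0.69 for the combination.

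**Figure D1:**
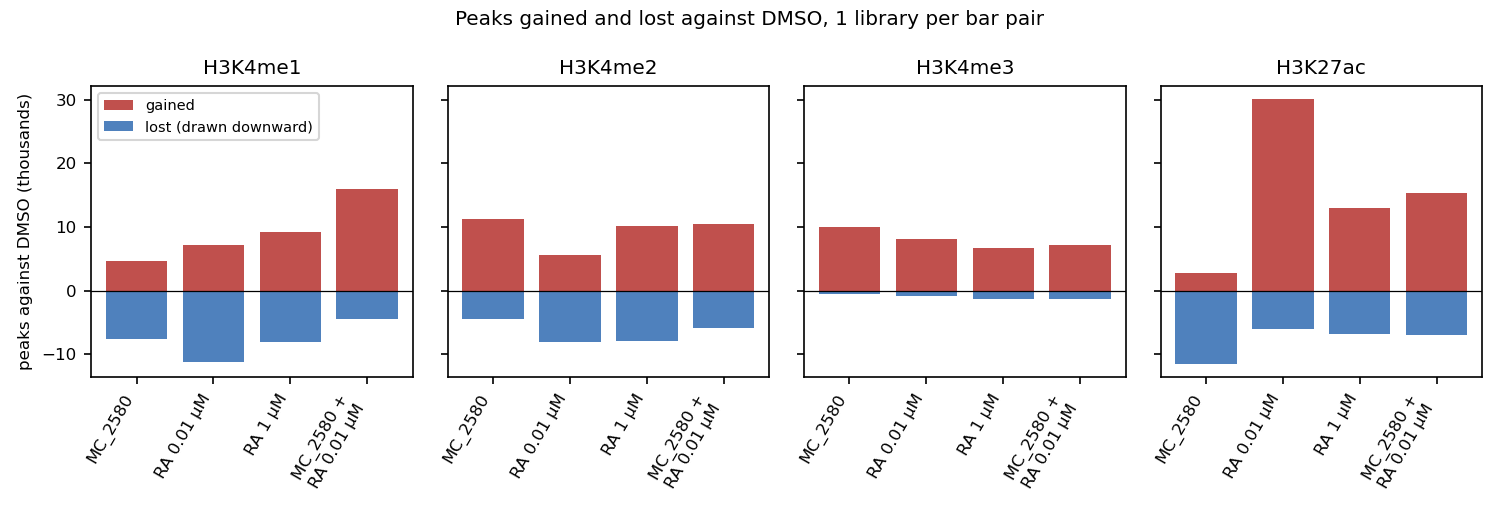
Numbers of peaks gained (red, upward) and lost (blue, downward) against DMSO for each mark and treatment, with 1 library per condition and therefore no error bars. H3K4me3 has 478 to 1365 losses in every treatment, and H3K27ac loses 11474 peaks with MC_2580 and gains 30048 with RA at 0.01 µM.

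Windows of H3K27ac change were followed across all lists. In the window on chromosome 20 from 48400001 to 48500000, the combination gained 17 H3K27ac peaks, more than in any other window. H3K27ac was called there 3 times in DMSO, 4 times with MC_2580, 20 times with RA at 0.01 µM, 17 times with RA at 1 µM and 21 times in the combination. H3K4me1 counts in the same window were 9, 10, 14, 13 and 20, and H3K4me3 counts were 1, 1, 6, 6 and 5. RA at 1 µM gained most on chromosome 11 from 45500001 to 45600000, with 16 gains. RA at 0.01 µM gained most on chromosome 10 from 134700001 to 134800000, where 18 peaks were called in that library, 1 in the combination and none in the other 3 H3K27ac lists. With MC_2580 the window on chromosome 1 from 10600001 to 10700000 lost 12 peaks, with 16 calls in DMSO and 5 with MC_2580. The window on chromosome 4 from 40300001 to 40400000 held 7 gains, its highest count, which 1 other window shared, and had 3 H3K27ac peaks in DMSO, 10 with MC_2580, 5 and 2 with RA at 0.01 and 1 µM, and 16 in the combination. On chromosome 22 from 48300001 to 48400000, RA at 1 µM and the combination each lost 11 of the H3K27ac peaks called in DMSO.

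**Figure D2:**
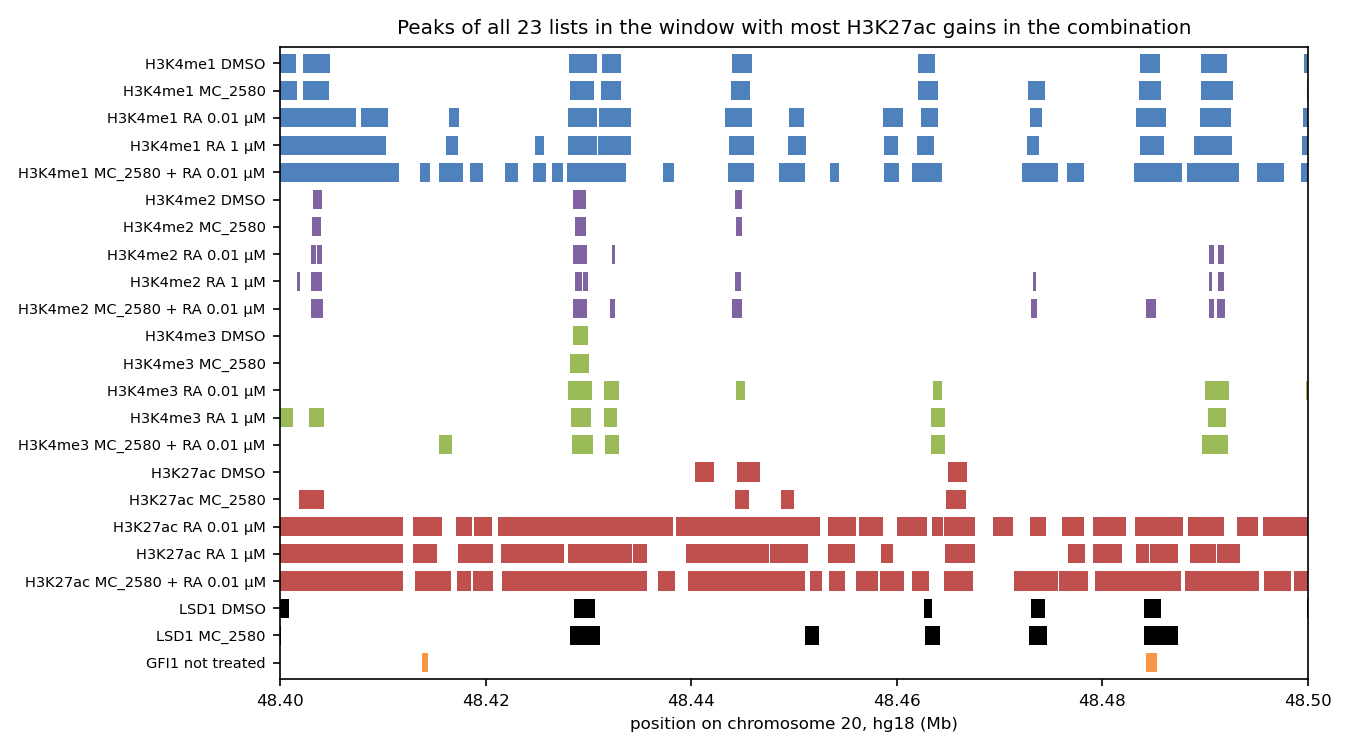
Peaks of all 23 lists (1 line each, colored by antibody) in the window of chromosome 20 from 48400001 to 48500000 on hg18 (position in Mb on the horizontal axis); each bar spans a called peak. H3K27ac has 3 peaks in DMSO and 4 with MC_2580 against 20, 17 and 21 in the conditions with RA at 0.01 µM, RA at 1 µM and the combination.

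The next comparison asked whether the combination came closer to RA at 1 µM than RA at 0.01 µM alone did. The Jaccard index, the bases shared by both lists over the bases covered by either, was 0.627 for H3K27ac between the combination and RA at 1 µM and 0.458 between the RA doses. The same index with RA at 1 µM was 0.545 for DMSO and 0.466 for MC_2580. The methylation marks showed no such gap: the index with RA at 1 µM was 0.752 for the combination and 0.754 for RA at 0.01 µM in H3K4me1, 0.732 and 0.747 in H3K4me2, and 0.757 and 0.783 in H3K4me3. With lists of equal length the H3K27ac indices were 0.652 and 0.503, and with peaks on H3K4me1 only, a choice made after the data were seen, they were 0.666 and 0.550. DMSO with RA at 1 µM had 0.555 and 0.576 in these settings. The combination was thus above DMSO each time, and RA at 0.01 µM below it. The gap between the combination and RA at 0.01 µM rests on 1 low-dose H3K27ac library that was less like RA at 1 µM than DMSO was. The H3K4me1 difference, combination minus RA at 0.01 µM, turned to 0.00302 with lists of equal length, and the H3K4me2 difference to 0.00549 with peaks reduced to 500 bases on either side of their centre and to 0.0149 when regions were counted instead of bases.

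**Figure D3:**
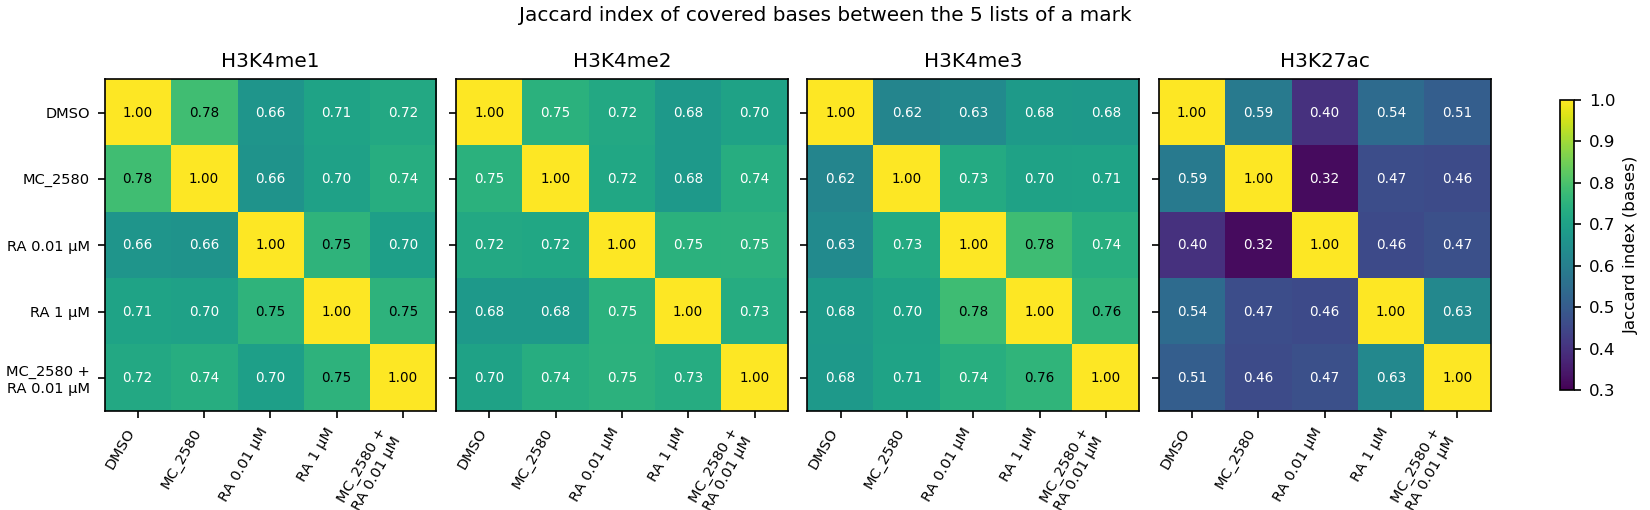
Jaccard index of covered bases between every pair of the 5 lists of a mark, as numbers and color, with the conditions on both axes. In H3K27ac the combination and RA at 1 µM reach 0.627, and RA at 0.01 µM with MC_2580 is the lowest pair at 0.321.

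Regions gained by RA at 1 µM and by the combination were then intersected. In H3K27ac, 5676 regions absent in DMSO were called in both, which is 54.3% of the 10444 gained with RA at 1 µM and 44.9% of the 12646 gained in the combination. Independent lists among the 37398 regions absent in DMSO would share 3532, and among all 64195 regions of the 5 lists 2057. Each region of the first set was gained in at least 1 treatment, which raises that number, and the second set holds regions that cannot be gained, which lowers it. Both are given below in this order, and an overlap that lies between them was not placed above or below independence. In 1000 simulations of unchanged libraries that share the DMSO control, the pair shared 4065 to 4489 regions, with 10276 and 10946 gained on average. RA at 0.01 µM, with 27889 gained regions, shared 5841 with RA at 1 µM, which is 55.9% of the same 10444 (7788 and 4537 for independent lists, 5724 to 6205 simulated with 15623 gained). In H3K4me1 the combination shared 6111 regions, 73.6% of the gains with RA at 1 µM (6423 and 1751 independent, 3354 to 3736 simulated), and RA at 0.01 µM 3981, 48.0% (2702 and 737 independent, 2543 to 2908 simulated). H3K4me2 had 4750, 56.2%, in the combination (4285 and 1509 independent, 2317 to 2652 simulated) and 2915, 34.5%, with RA at 0.01 µM (2132 and 751 independent, 1938 to 2222 simulated). In H3K4me3 the order was the other way, with 3269, 54.7%, in the combination (2591 and 1094 independent, 1732 to 1988 simulated) and 4204, 70.3%, with RA at 0.01 µM (3101 and 1309 independent, 1830 to 2093 simulated). The simulated sets do not keep the numbers of gained regions, which for the combination in H3K4me1 were 7725 simulated and 15006 observed, so a gap to them is not read as a shared effect. Of the 2149 H3K27ac regions gained with MC_2580, 1093 (50.9%) were also gained in the combination (727 and 423 for independent lists), 698 (32.5%) with RA at 1 µM (600 and 350) and 1013 (47.1%) with RA at 0.01 µM (1603 and 934). The simulated sets gained 6566 regions with MC_2580 and give no reference for these numbers. Of the 15266 H3K27ac peaks gained in the combination, 57.0% were also called with RA at 0.01 µM, 48.6% with RA at 1 µM and 9.72% with MC_2580, and 26.0% (25.3 to 26.7%) were called in no other treatment. As merged regions, RA at 0.01 µM and the combination shared 6596 gains, between the 9431 and 5494 of independent lists. The 5676 shared with RA at 1 µM lay above both of its references. The larger share with RA at 0.01 µM is thus not read as closer likeness. Part of any excess over independent lists may come from the shared DMSO library, which could not be split.

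For LSD1 itself the question was whether its occupancy differed with the inhibitor. Of the 12562 DMSO peaks, 11584 (92.2%, 91.7 to 92.7%) overlapped a peak with MC_2580 and 978 did not, while 7797 of the 18822 MC_2580 peaks (41.4%, 40.7 to 42.1%) had no DMSO counterpart. Both lists had been filtered before deposit, so a missing counterpart may have been called and then removed. The 3 highest-scoring retained peaks lay on chromosome 5 from 138024312 to 138027383, chromosome 19 from 50985465 to 50987767 and chromosome 10 from 73722400 to 73730141, each with GFI1. Their scores, 3202 to 3233, lie above 3100, so they may not be the strongest retained peaks. All 3 highest-scoring gained peaks were neighbours on chromosome 19, from 53743055 to 53750889, from 53750934 to 53756420 and from 53756491 to 53764307, and each overlapped GFI1 peaks. A window on chromosome 11 from 63800001 to 63900000 held 8 gained LSD1 peaks, the highest count, which 1 other window shared. Lost peaks were narrower than retained ones, with median widths of 1232.5 and 2208 bases, and 23.1% of them carried H3K4me3 in DMSO against 61.6% of all LSD1 peaks. The retained share of DMSO peaks was 80.6% with lists of equal length and 74.0% with a 50% reciprocal overlap. The share of MC_2580 peaks without a DMSO counterpart was 24.2% with lists of equal length and 63.0% with a minimum score of 357 in both lists, a choice made after the data were seen.

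GFI1 and LSD1 shared many sites. A GFI1 peak overlapped 56.8% (55.9 to 57.7%) of DMSO LSD1 peaks, above all 1000 circular shifts of the GFI1 peaks along their chromosomes, which gave 2.64 to 4.93%. With MC_2580 the share was 44.7% (shifts 3.05 to 5.63%), but of a longer list. There 8421 of 18822 LSD1 peaks had GFI1, against 7134 of 12562 in DMSO. Within H3K4me2 regions of DMSO, 62.1% of GFI1 peak centres fell inside DMSO LSD1 peaks, against 28.9 to 35.1% in shifts along those regions. Inside MC_2580 LSD1 peaks it was 80.0%, against 52.7 to 58.4% in shifts. GFI1 was found at 58.0% of the MC_2580 LSD1 peaks shared with DMSO and at 26.1% (25.1 to 27.1%) of those without a DMSO counterpart. Conversely 30.0% of GFI1 peaks overlapped DMSO LSD1, 49.7% of those with a score of at least 100 and 20.5% of the weaker ones. MC_2580 LSD1 peaks overlapped 37.7% of GFI1 peaks. Of 12 shared GFI1 peaks tied at the top score, the first 3 by position lay on chromosome 3 from 58431222 to 58433306, chromosome 6 from 58883668 to 58887809 and chromosome 8 from 128807703 to 128824391. At the chromosome 3 peak, H3K27ac was called with MC_2580 and in the combination and in no other condition. Of 18 GFI1 peaks tied at the top score outside DMSO LSD1 peaks, the first 3 by position, on chromosome 1 from 91625221 to 91625877, from 121184549 to 121187106 and from 141476812 to 141484095, had no H3K27ac or H3K4me2 peak in any condition. Whether any of the top-scoring GFI1 peaks named here is a false call was not tested. The share of DMSO LSD1 peaks with GFI1 was 34.6% with a minimum score of 100 and 22.6% with a 50% reciprocal overlap, and that of MC_2580 peaks 23.5 and 7.14%, an overlap which the narrower GFI1 peaks (median 752 bases) seldom meet.

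LSD1 peaks with GFI1 were lost more often under MC_2580 than those without. With GFI1, 90.2% (89.5 to 90.9%) of 7134 peaks were retained, and without GFI1 94.8% (94.2 to 95.4%) of 5428, a difference of 4.63 percentage points. In quartiles of LSD1 score from lowest to highest, retention was 78.0, 86.5, 92.5 and 96.8% with GFI1 and 89.4, 95.6, 99.5 and 99.8% without, with separate intervals in each. In the top quartile 82 peaks with GFI1 and 1 without were lost. In quartiles of peak width, strata added after the lists were seen, the difference ran from 20.8 points in the narrowest to 0.0522 in the widest. In strata by histone mark, chosen after the data were seen, the difference was larger at sites without the mark. Retention was 70.5% with and 85.7% without GFI1 where H3K27ac was absent in DMSO, and 96.4 and 96.9% where it was present, with overlapping intervals. The 3 highest-scoring lost peaks all had GFI1. On chromosome 13 from 76354180 to 76355300, H3K4me1 was called with MC_2580 and in the combination only, H3K4me3 with MC_2580, RA at 1 µM and the combination, and H3K27ac in the combination only. On chromosome 7 from 145237593 to 145238385, H3K4me2 and H3K4me3 were called with MC_2580 and in the combination only. On chromosome 13 from 110176499 to 110177705, H3K27ac was called in the combination only. A 50% reciprocal overlap gave a difference of 19.8 points and lists of equal length 2.95 points.

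**Figure D4:**
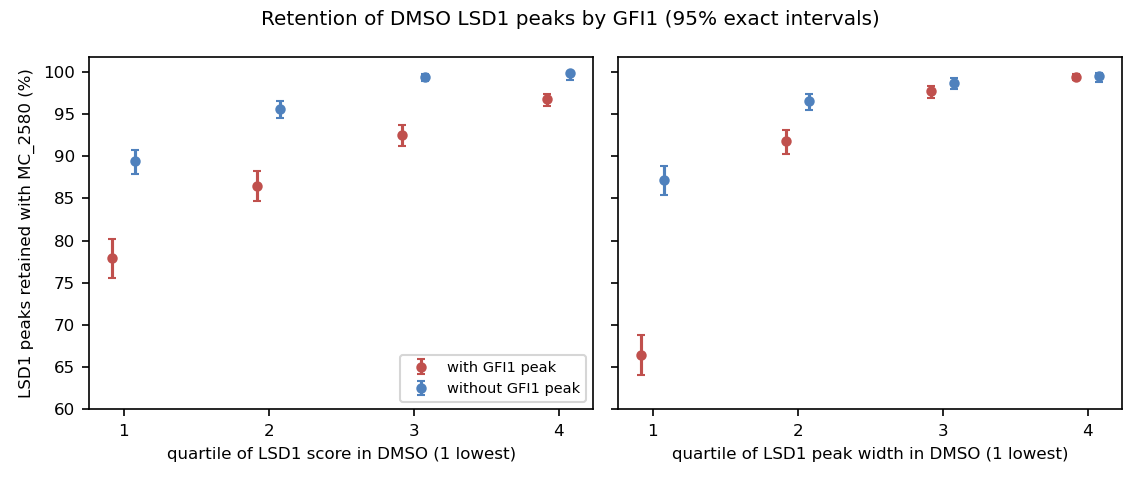
Share of DMSO LSD1 peaks retained with MC_2580 (vertical axis, %, starting at 60) by quartile of LSD1 score (left) and of LSD1 peak width (right), for peaks with (red) and without (blue) a GFI1 peak, with 95% exact intervals as bars. In the lowest score quartile retention is 78.0% with and 89.4% without GFI1, and in the highest width quartile 99.5% in both.

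The last comparison followed the histone marks at the 12562 LSD1 sites of DMSO cells, split by H3K4me3 in DMSO into 7742 promoter-type and 4820 distal-type sites. At distal-type sites with GFI1, H3K4me2 was called at 47.8% (45.9 to 49.7%) in DMSO, 71.8% (70.0 to 73.5%) with MC_2580 and 64.2% in the combination, but at 39.2 and 41.9% with RA at 0.01 and 1 µM. Distal-type sites without GFI1 had 49.5% in DMSO, 62.7% with MC_2580 and 60.1% in the combination. The change with MC_2580 was thus larger with GFI1 by 10.7 percentage points (8.28 to 13.2), and that of the combination by 5.79 points (3.26 to 8.33). H3K4me3, absent from these sites in DMSO by definition, was called at 49.1% of those with GFI1 and 38.0% of those without under MC_2580, and at 37.7 and 28.5% in the combination. RA alone went the other way, with H3K4me3 at 23.1% with and 26.7% without GFI1 at 0.01 µM and at 18.4 and 21.3% at 1 µM. As these sites were chosen for lacking H3K4me3 in DMSO, a rise in every treatment was fixed by the choice. H3K27ac moved differently: with GFI1 it was called at 52.4% in DMSO, 53.5% with MC_2580 and 67.5% in the combination, and without GFI1 at 69.0, 55.6 and 74.0%. RA alone gave H3K27ac shares of 46.7% (0.01 µM) and 50.9% (1 µM) with GFI1 and 74.3 and 70.9% without. At promoter-type sites H3K27ac was called at 90.2% in DMSO, 86.1% with MC_2580 and 93.7% in the combination. For comparison, in a set chosen after the data were seen, 27500 H3K4me1 regions of DMSO with neither LSD1, GFI1 nor H3K4me3 had H3K4me2 at 13.2% in DMSO and 17.2% with MC_2580, and H3K27ac at 25.9, 14.6 and 32.6% in DMSO, MC_2580 and the combination. H3K4me3, again absent in DMSO by definition, was called in that set at 7.36% with MC_2580 and 6.08% in the combination. With RA at 0.01 and 1 µM it was at 8.23 and 6.19%. Over all DMSO peaks, 89.0% of H3K4me2 and 65.0% of H3K27ac peaks were retained with MC_2580, and the MC_2580 lists covered 1.94% and 3.10% of the genome span. A 50% reciprocal overlap turned the GFI1 difference in H3K27ac with MC_2580 from 14.5 to -0.55 points and that in H3K4me3 from 11.1 to -0.32, and took those of the combination from 10.1 to 1.91 points in H3K27ac and from 9.16 to 0.866 in H3K4me3.

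**Figure D5:**
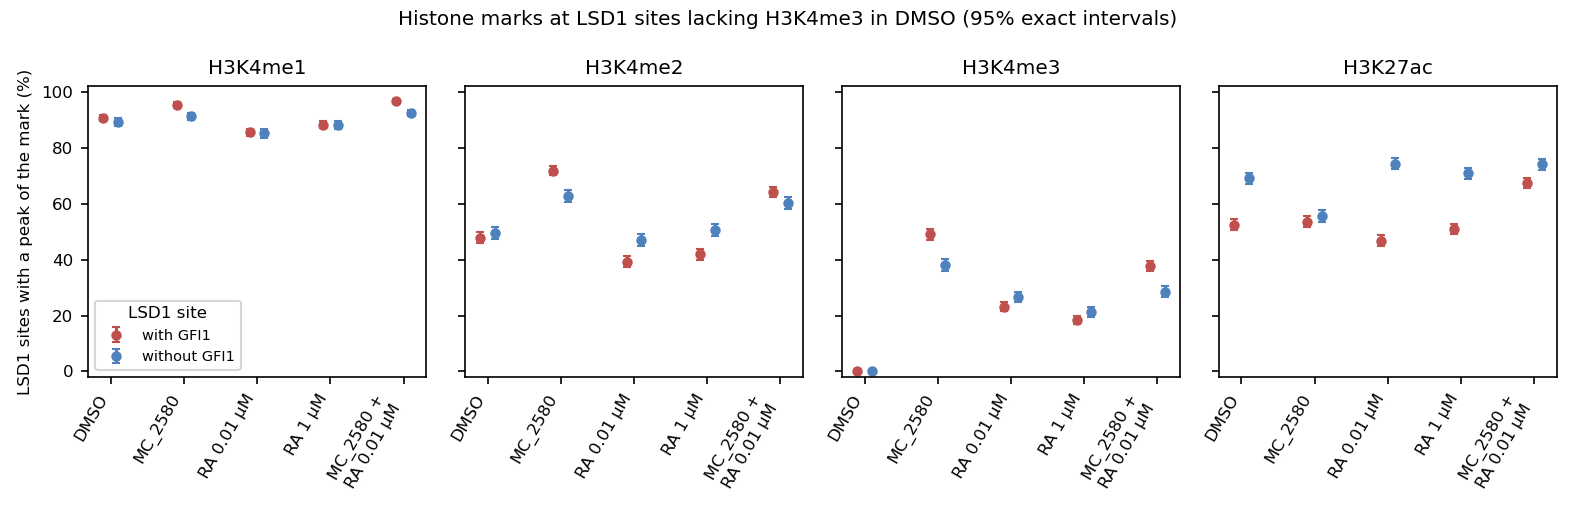
Share of distal-type LSD1 sites (no H3K4me3 in DMSO) with a peak of each mark, in %, in the 5 conditions, for 2637 sites with (red) and 2183 without (blue) a GFI1 peak; bars are 95% exact intervals. H3K4me2 is at 71.8% with GFI1 and 62.7% without under MC_2580, and H3K27ac at 53.5 and 55.6%.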

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

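A single minimum score for both LSD1 lists and H3K27ac peaks on H3K4me1 only were chosen after the data were seen, and the other alternatives were fixed before. Each group had 1 library, so leaving out a replicate was not possible. No paired analysis was possible because each antibody and condition had 1 library and the labels give no pairs. Depth per library is not given in the sources used here, so a list may be longer for technical reasons: the share of MC_2580 LSD1 peaks absent from DMSO was 24.2% at equal list length. A region without a call may also have been below detection. Alternative promoter windows for gene lists were not run. A minimum score of 100 and the one-sided threshold removed no LSD1 peak and therefore tested nothing in the LSD1 lists.

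Of 68 alternative log2 ratios of gained over lost peaks, 66 kept their direction, as did 14 of 17 Jaccard differences, 36 of 40 differences in change at distal LSD1 sites, and each of the 5 differences in LSD1 retention by GFI1. Of 46 alternative peak numbers per library, under a minimum score of 100 and on autosomes, 44 stayed within 1.5 times the reported number. The other 2, at a minimum score of 100, were 36469 H3K27ac peaks with RA at 0.01 µM and 9664 GFI1 peaks. The directions that turned were those of the log2 ratio of H3K4me1 with RA at 0.01 and 1 µM, of the Jaccard difference in H3K4me1 and H3K4me2, and of the change at distal sites in H3K4me1, H3K4me3 and H3K27ac. Except where the construction of the alternative is named, the cause was not tested.

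The log2 ratios are given for MC_2580, RA at 0.01 µM, RA at 1 µM and the combination in this order. With a minimum score of 100 they were -0.93, -1.41, -0.012 and 2.40 in H3K4me1, 2.70, -0.17, 1.04 and 1.75 in H3K4me2, 6.38, 4.68, 3.19 and 2.93 in H3K4me3, and -2.48, 2.23, 1.18 and 1.19 in H3K27ac. A 50% reciprocal overlap gave -0.47, 0.22, 0.57 and 1.31 in H3K4me1, 1.03, -0.15, 0.47 and 0.48 in H3K4me2, 1.60, 1.31, 1.17 and 1.29 in H3K4me3, and -1.22, 1.28, 0.56 and 0.69 in H3K27ac. It asks more of each overlap and so raises both gained and lost numbers. With peaks within 1 kb joined they were -0.70, -0.51, 0.26 and 1.91 in H3K4me1, 1.175, -0.49, 0.32 and 0.90 in H3K4me2, 4.28, 3.14, 2.29 and 2.35 in H3K4me3, and -1.89, 2.25, 0.93 and 1.16 in H3K27ac. The one-sided threshold gave -0.89, -1.12, 0.36 and 3.12 in H3K4me1, 3.29, -0.012, 1.15 and 2.18 in H3K4me2, 7.58, 5.46, 3.78 and 4.11 in H3K4me3, and -2.61, 2.37, 1.36 and 1.43 in H3K27ac. H3K27ac peaks on H3K4me1 only gave -2.17, 1.16, 1.09 and 1.24.

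The Jaccard difference, combination minus RA at 0.01 µM in their index with RA at 1 µM, moved with a minimum score of 100 to -0.0069 in H3K4me1 and -0.017 in H3K4me3. At equal list length it turned to 0.00302 in H3K4me1 and was 0.149 in H3K27ac. With peaks reduced to their centre it turned to 0.00549 in H3K4me2 and was -0.038 in H3K4me3 and 0.111 in H3K27ac. Over regions it was -0.013 in H3K4me1, 0.0149 in H3K4me2, a turn, and -0.037 in H3K4me3. On H3K4me1 only it was 0.116 in H3K27ac. Shared gains of RA at 1 µM and the combination were 83.7, 65.6, 61.4 and 59.9% in H3K4me1, H3K4me2, H3K4me3 and H3K27ac with a minimum score of 100, and 57.8% in H3K4me2 and 55.5% in H3K27ac with peaks joined.

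For LSD1, a 50% reciprocal overlap gave 74.0% of DMSO peaks retained, 50.6% of MC_2580 peaks absent from DMSO, GFI1 at 22.6% of DMSO and 7.14% of MC_2580 peaks, and a retention difference of 19.8 points. A minimum score of 100, which removes GFI1 peaks, gave GFI1 at 34.6 and 23.5% and a difference of 6.19 points. With peaks joined, 40.6% of MC_2580 peaks were absent from DMSO and GFI1 lay at 57.8 and 45.9%. Equal list length gave 80.6% retained, 24.2% absent, GFI1 at 52.1% of MC_2580 peaks and a difference of 2.95 points. A single minimum score gave 95.8% retained, 63.0% absent and GFI1 at 66.5% of DMSO peaks, as it removes weak DMSO peaks only.

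The change at distal LSD1 sites with GFI1 minus without was, with a minimum score of 100, 4.86 points with MC_2580 and 5.08 in the combination for H3K4me1, and 8.11 and 6.42 for H3K4me3. A 50% reciprocal overlap turned it to -2.83 and -0.578 for H3K4me1, to -0.322 with MC_2580 for H3K4me3 and to -0.553 with MC_2580 for H3K27ac, and left 0.866 and 1.91 in the combination for H3K4me3 and H3K27ac. H3K4me3 with MC_2580 was 7.61 at equal list length, and H3K27ac with MC_2580 was 10.8 with peaks reduced to their centre. For H3K4me2 no alternative moved the difference beyond its interval.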

Other observations

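The tests chosen only after the result was seen were the share of H3K27ac peaks on H3K4me1, in all gained peaks and at equal list length, the reading of the planned score quartiles as a test of weaker LSD1 peaks, LSD1 retention by H3K4me1 and H3K27ac, and retention weighted to equal scores or to equal width and H3K4me3, while the single minimum score and the strata by width and H3K4me3 were added after the lists were seen but before their own result.

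The 15266 H3K27ac peaks gained in the combination lay on H3K4me1 in 48.3% of cases in DMSO, 49.0% with MC_2580, 49.5% with RA at 0.01 µM, 54.8% with RA at 1 µM and 64.0% in the combination. For H3K4me2 the shares in the same order were 16.6, 20.2, 17.8, 20.6 and 24.3%, and for H3K4me3 9.87, 15.8, 16.1, 14.5 and 16.9%. H3K27ac peaks of 20 kb or wider numbered 332 in DMSO, 174 with MC_2580, 538 and 399 with RA at 0.01 and 1 µM and 372 in the combination. The widest lay on chromosome 2 from 43247803 to 43310408 in DMSO and from 43247820 to 43310454 with MC_2580, and on chromosome 10 from 73090391 to 73189024 with RA at 0.01 µM and from 73106005 to 73188733 with RA at 1 µM. In the combination the widest was on chromosome 19 from 53776994 to 53864240, close to the 3 gained LSD1 peaks named in the report.

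In quartiles of score from lowest to highest, 79.6, 57.3, 25.7 and 3.02% of MC_2580 LSD1 peaks were absent from DMSO. GFI1 lay at 22.2, 26.7, 34.0 and 47.9% of the absent peaks and at 54.4, 48.5, 52.1 and 67.4% of the shared ones. GFI1 peaks outside DMSO LSD1 peaks carried H3K4me1 in DMSO in 42.6% of cases, against 95.6% inside, and H3K27ac in 26.7 against 76.6%. The LSD1 peaks lost with MC_2580 carried H3K4me2 in 38.4% of cases in DMSO and 57.2% with MC_2580, and H3K4me3 in 23.1 and 41.9%.

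The H3K27ac list of RA at 0.01 µM was longer than the other 4 H3K27ac lists and less like them. Low specificity of this library may be a cause, since 35.5% of its gained peaks lay on H3K4me1 of any condition, under the lowest share of the other treatments, 64.4%. At equal list length its Jaccard index with RA at 1 µM was 0.503, just above the lower of the DMSO and MC_2580 indices, 0.4998. By that test, length alone stays open for an index with RA at 1 µM below both, as in the full lists. The index remained below that of DMSO, 0.555, so equal length did not remove that gap. With DMSO and MC_2580 its equal-length indices were 0.450 and 0.398, and no pair among the other lists was below 0.4998. Equal length thus did not remove the low likeness to DMSO and MC_2580. Over all peaks of this list, the share on H3K4me1 of any condition was 60.7%, against at least 83.1% in the other 4 lists. At equal length it was 85.3% against at least 90.6%. The gap was smaller at equal length but remained, so these values argue against length as its whole cause, not as part of it. An effect of the low RA dose cannot be told apart from a property of this library, as that dose had 1 H3K27ac library.

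LSD1 peaks with GFI1 were lost more often with MC_2580 than those without. Weaker, narrower or promoter-poor peaks were argued against from the start, since peaks with GFI1 had higher scores (median 487 against 343), were wider (2315 against 1942 bases) and more often carried H3K4me3 (63.0 against 59.8%). Within strata the difference was at least 3.08 points in each score quartile, and its smallest value over 6 strata of width and H3K4me3 was 0.0522 points. From the narrowest to the widest quartile it was 20.8, 4.78, 0.977 and 0.0522 points, with overlapping intervals in the third and the widest. The narrowest quartile held 523 of the 698 lost peaks with GFI1, so the difference lay mostly among narrow peaks. Weighting to equal scores gave 7.63 points and weighting to equal width and H3K4me3 6.22 points. Unequal minimum scores were argued against as the whole cause by 4.58 points with a single minimum score. That setting removed DMSO peaks only and brought back no filtered MC_2580 call, so it cannot decide on the filter itself. Sites outside marked chromatin were argued against as the whole cause by 3.16 points among sites with H3K4me1. The difference was however 43.8 points without H3K4me1 and 0.459 where H3K27ac was called. The filter applied to the LSD1 lists before deposit, depth of the LSD1 libraries, false peaks common to GFI1 and DMSO LSD1, and an effect of the inhibitor on LSD1 at GFI1 sites were not tested and stay open.

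H3K4me2 was gained with MC_2580 more often at distal LSD1 sites with GFI1 than at those without. A longer MC_2580 list was argued against by a difference of 9.52 points (interval 2.32 on either side) at equal list length. Stronger LSD1 peaks were argued against by differences of 6.51 to 16.7 points over the score quartiles. RA alone moved H3K4me2 the other way, with differences of -6.00 points at 0.01 µM and -6.96 points at 1 µM. An effect of the inhibitor through LSD1 at GFI1 sites was not tested, and it stays open with library quality and unknown depth, as each condition had 1 library.

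It was asked whether regions that gain H3K4me2 with MC_2580 are those that take up H3K27ac in the combination. Of 5776 such regions without H3K27ac in DMSO, 28.8% (27.7 to 30.0%) had H3K27ac in the combination, against 30.0% of 11095 regions with H3K4me2 in both DMSO and MC_2580. By the rule fixed beforehand the answer was negative. With MC_2580 alone the shares were 11.4 and 7.72%, and with RA at 0.01 µM alone 28.5 and 39.3%. As the 2 sets already differed with RA at 0.01 µM alone, their similar shares in the combination leave the question undecided.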
